A study of Homo sapiens with 12 samples.

How the data were processed

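RNA-seq was measured in 12 libraries of human hepatoma cell lines, in 4 groups of 3, labelled Hep-3B or Huh-7 and negative-control siRNA or siARD1. Per the labels, total RNA was extracted with Trizol, depleted of rRNA and made into directional libraries. Per the labels, the authors trimmed reads with cutadapt 4.6 and aligned them with STAR 2.7.11b to GRCh38. The deposited tables, one per line, hold raw counts per Ensembl gene. The counting tool, annotation release and strand setting are not given in the sources used here. All columns of values were mapped to a sample, with 0 left over. The tables list 25720 genes (Hep-3B) and 25714 (Huh-7), of which 25701 and 25698 had a symbol and 23740 and 23662 were found in GENCODE v29, used here for positions, gene types, GC content and length. Total counts ran from 17327615 to 25960237 per library. Intervals cover spread between libraries as labelled, since the labels do not say whether replicates were separate cultures, and each p-value measures only that spread.

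Each line was analysed alone in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 15762 and 15919 genes, libraries were scaled with TMM factors, and siARD1 was compared with control by a robust quasi-likelihood F-test. P-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05, and genes past it are called changed. Log2 fold changes are siARD1 minus control. Their SE was derived as the absolute log2 fold change over the square root of F. It is an approximation, and a poor one where a group holds few counts. CPM are TMM-scaled. The remaining share of NAA10 and its 95% interval come from the fitted fold change and this SE (z of 1.96), so the interval is approximate. An exact two-sided permutation test over 6 libraries cannot give a p under 0.1. The difference between the lines was the interaction in one edgeR fit of the 4 groups. Shared changes were counted among genes tested in both lines, against the product of the counts over the number tested, with Fisher's exact test.

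In all, 37 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. The rule names 14 genes whatever their result, the 8 largest rises and 8 largest falls per line among protein-coding changed genes with a mean of at least 5 CPM and no overlap between groups, up to 3 members per list by p, and between lines the 6 largest shared rises, shared falls and differences each way. Some genes and lists that the rule or the lists name are not reported here. Genes named outside this rule are said to be so where they stand.

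Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fold of at least 1.5, a false discovery rate of 0.01, both lines in one fit, lists without members of another list, and each library left out in turn. Alternatives for normalized values were not used here, since the tables hold counts. Carry-over between the lines was estimated from genes at 100 CPM or more in one line and at least 1000-fold lower in the other. Trends on GC content and length were removed with a smooth surface over all tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

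The steps were tested on simulated data with 50 genes changed at each of 4 sizes per line. At log2 changes of 0.3, 0.5, 1 and 2, the fit recovered 50, 78, 100 and 100% in the first line with 6 false calls, and 40, 84, 98 and 100% in the second with 10. The test of the difference recovered 246 of 384 genes with 10 false calls. A list shifted by 0.5 was called in both lines with 0 others. The simulated genes varied independently, so this does not show how often camera calls lists whose members vary together. Single changed genes were planted only at a mean count of at least 20, and all genes had the same spread (dispersion 0.005). Recovery in weaker or more variable genes is therefore not shown. Removal of a planted GC trend took its Spearman rho from -0.386 to 0.000643, and a planted 7-mer ranked 1 of 16384.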

Results

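Gene-level RNA-seq counts were compared in 12 libraries from human hepatoma cells, 6 labelled Hep-3B and 6 labelled Huh-7. In each line, 3 libraries came from cells given a negative-control siRNA and 3 from cells given an siRNA against ARD1 (siARD1). ARD1 is the older name of NAA10, the catalytic subunit of the NatA complex, which acetylates protein N termini. The interest stated for the series is the part of ARD1 in making glutathione and in the escape of liver cancer cells from ferroptosis, an iron-dependent death driven by lipid peroxidation. In the libraries labelled Hep-3B, total counts were 22881482, 17395771 and 21061308 for the controls and 17340075, 22674899 and 25960237 after siARD1. In the Huh-7 libraries they were 17327615, 22011675 and 22674749 for the controls and 19514591, 19167607 and 19764412 after siARD1. Hep-3B is known as a line that secretes alpha-fetoprotein and albumin. The 6 libraries labelled Hep-3B held 0.265 to 1.97 CPM (counts scaled to library size) of AFP and 0.573 to 6.15 of ALB. The Huh-7 libraries held 3199 to 5276 CPM of AFP and 10745 to 12839 of ALB. Whether the 6 libraries come from Hep-3B is therefore in doubt, and the text names them by their label only.

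The first comparison asked which mRNAs changed in the libraries labelled Hep-3B when ARD1 was lowered. NAA10 (ENSG00000102030, GRCh38 chromosome X, 153929242 to 153935223) fell from 55.3 ± 5.94 to 13.6 ± 2.47 CPM (SD, n = 3 each), a log2 fold change of -2.01 (SE 0.12, edgeR adjusted p = 1.36e-07), which left 24.9% of the control level (95% interval 21.2 to 29.3). The exact two-sided permutation test over the 6 libraries gave p = 0.1, the smallest this design allows. The largest rise among well-expressed genes was in SPX, the precursor of the peptide hormone spexin, from 3.57 to 29.3 CPM (log2 fold change 3.06). Next came the tight junction gene CLDN1 (2.13), the transporter gene SLC16A9 (1.81), the secretory pathway gene IER3IP1 (1.81), FBXW10B (1.80), the chaperone gene CLGN (1.79), ABCA10 (1.68) and the semaphorin gene SEMA7A (1.59), with SEs of 0.11 to 0.33 and edgeR adjusted p from 2.73e-08 to 0.00445. Falls were ranked by the same rule, among protein-coding genes with a mean of at least 5 CPM. After NAA10, the largest were in the plasma protein gene ITIH2 from 108 to 37.0 CPM (-1.55), CYTIP (-1.51), the histone gene H4C8 (-1.45), the fibrinogen gene FGA from 229 to 84.4 CPM (-1.44), RARRES1 (-1.40), the linker histone gene H1-2 (-1.39) and CLIC3 (-1.34). Their SEs were 0.09 to 0.16 and edgeR adjusted p from 1.35e-07 to 0.000323. FBXW10B and the histone genes have near-identical relatives in the genome, so the share of reads given to each is uncertain.

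**Figure D1:**
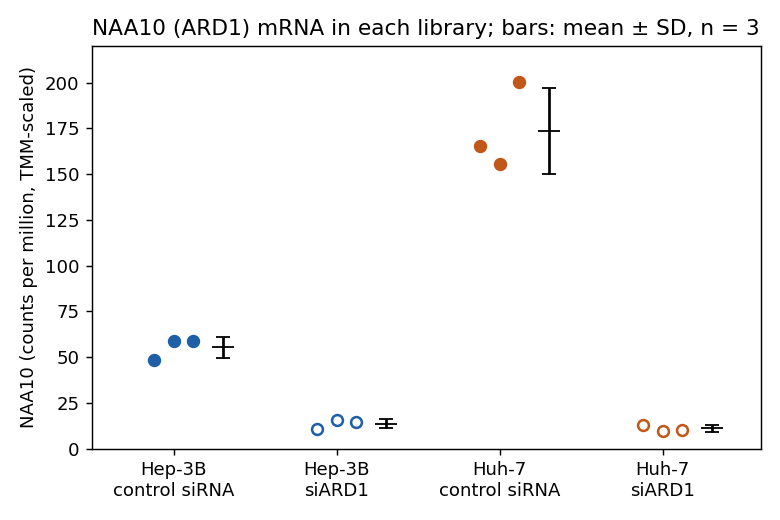
NAA10 in each library, in TMM-scaled CPM on a linear axis from 0. Filled points are control libraries, open points siARD1 libraries, and bars the mean ± SD of 3 libraries. The means fell from 55.3 to 13.6 in the libraries labelled Hep-3B and from 174 to 11 in Huh-7.

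Genes of secreted liver proteins and of histones fell in the libraries labelled Hep-3B. Of 18 tested members 14 fell and 0 rose (median log2 fold change -1.08), with FGB from 325 to 137 CPM (-1.24), FGA, ITIH2 and the complement gene C3 (-1.08) among them (camera adjusted p = 5.39e-07, and adjusted p = 0.434 with an estimated correlation). In the same libraries, 28 genes that are abundant in Huh-7 and almost absent here stood at 0.0463% of their Huh-7 level in the controls and at 0.0156% after siARD1. The control libraries (0.0407 to 0.0569%) and the siARD1 libraries (0.0147 to 0.0168%) did not overlap in this background. The 28 genes include members of the list, ALB and AFP among them, so this fall is not independent of the list. The 17 genes outside the list had a median of 0.0466% in the controls and 0.0211% after siARD1. Among those 17, A2M fell (0.0443 to 0.00252%) and COL2A1 did not (0.0466 to 0.0700%). The labels do not say whether these groups were prepared together, so a difference in handling cannot be told apart from siARD1 in this line. ALB (5.05 to 0.796 CPM) and AFP were among the list members at such traces. Of the 12 members for which this background predicts under 10% of the mean level, 10 fell and 0 rose. Replication-dependent histone genes fell in 11 of 13 (median -1.34), with H4C8, H1-2 and H2BC5 (-1.30) as examples (camera adjusted p = 1.61e-06, and adjusted p = 0.382 with an estimated correlation). Together the genes of the fixed histone list held 0.00958% of counts in the controls, and histone genes outside the list were not counted. That share is low for libraries labelled as total RNA depleted of rRNA. Whether the values cover transcripts without a poly(A) tail is therefore not settled.

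Genes of lipid synthesis fell as well. In cholesterol synthesis 19 of 25 members fell and 1 rose (median -0.50). Examples were FDFT1, which encodes squalene synthase (-0.72), and SREBF2, the gene of the sterol-responsive activator (-0.65), with camera adjusted p = 1.07e-06 and adjusted p = 0.509 with an estimated correlation. In fatty acid synthesis 11 of 19 fell and 2 rose (median -0.31). SREBF1, which encodes the lipogenic activator, fell by 1.17 on the log2 scale, the desaturase gene SCD by 1.04 and FADS2 by 0.86 (camera adjusted p = 0.000414, and adjusted p = 0.434 with an estimated correlation). In glycolysis 16 of 21 fell and 1 rose (median -0.26), among them PKM (-0.59) and ALDOC (-0.81), with camera adjusted p = 1.27e-05 and adjusted p = 0.382 with an estimated correlation. Of the hypoxia-induced genes 15 of 27 fell and 2 rose (median -0.26), among them CA9 (-0.84) and NDRG1 (-0.56), with camera adjusted p = 0.00161 and adjusted p = 0.509 with an estimated correlation. Cytosolic ribosomal protein genes fell in 24 of 49 (median -0.19), RPS14 among them (-0.41), with camera adjusted p = 3.86e-05 and adjusted p = 0.742 with an estimated correlation. Mitochondrially encoded mRNAs fell in 5 of 13 (median -0.17), MT-ND4L (-0.33) and MT-CO2 (-0.29) among them, with camera adjusted p = 0.00816 and adjusted p = 0.509 with an estimated correlation.

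Genes of the unfolded protein response rose in the libraries labelled Hep-3B, 20 of 23 with 0 falling (median 0.34). The ER chaperone partner gene DNAJB9 rose by 1.33, the ER degradation gene SEL1L by 1.18 and HYOU1 by 0.54 (camera adjusted p = 5.39e-07, and adjusted p = 0.382 with an estimated correlation). Targets of ATF4, the amino acid response activator, rose in 14 of 34 with 0 falling (median 0.28), among them the mitochondrial folate gene MTHFD2 (1.18) and the asparagine synthetase gene ASNS (0.66), with camera adjusted p = 0.000901 and adjusted p = 0.673 with an estimated correlation. Of NF-kB and acute inflammation genes 6 of 18 fell and 2 rose (median -0.25), among them the feedback inhibitors NFKBIA (-0.72) and TNFAIP3 (-0.58), with camera adjusted p = 0.0313 and adjusted p = 0.509 with an estimated correlation. That call was lost without control 2 (adjusted p = 0.0628), control 3 (0.0702) or siARD1 library 1 (0.0548).

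For the genes tied to glutathione and ferroptosis, both subunits of the cystine importer rose in the libraries labelled Hep-3B, SLC7A11 by 0.75 (SE 0.09, edgeR adjusted p = 3.49e-05) and SLC3A2 by 0.39 (0.08, 0.00122). The transferrin receptor gene TFRC rose by 1.38 (0.18, 0.00242) and ACSL4, which activates polyunsaturated fatty acids, by 0.26 (0.06, 0.00399). GCLC, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, fell by 0.39 (0.12, 0.0222). That call was lost without control 1 (adjusted p = 0.0893), control 3 (0.0735), siARD1 library 1 (0.0585) or siARD1 library 3 (0.0503). NAA15, the anchor subunit of NatA, rose by 0.58 (0.12, 0.00321) and its partner NAA50 by 0.81 (0.07, 1.16e-06). Log2 fold changes that did not pass were GCLM 0.23 (edgeR adjusted p = 0.208), GSS -0.17 (0.0844), GPX4 0.08 (0.359), AIFM2 0.09 (0.416), CTH 0.57 (0.110) and CBS 0.40 (0.551). GCLM passed without control 3 (0.35, edgeR adjusted p = 0.0430) and with no filter on low counts (0.00317), GSS with upper-quartile scaling (0.0373), and CTH without control 1 (0.35, 0.000648). In the glutathione synthesis and cystine supply list 5 of 15 members rose and 2 fell (median 0.23, camera adjusted p = 0.250). The median ran from 0.10 without control 1 to 0.35 without control 3, and was 0.092 once a trend on GC content and length was removed.

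**Figure D2:**
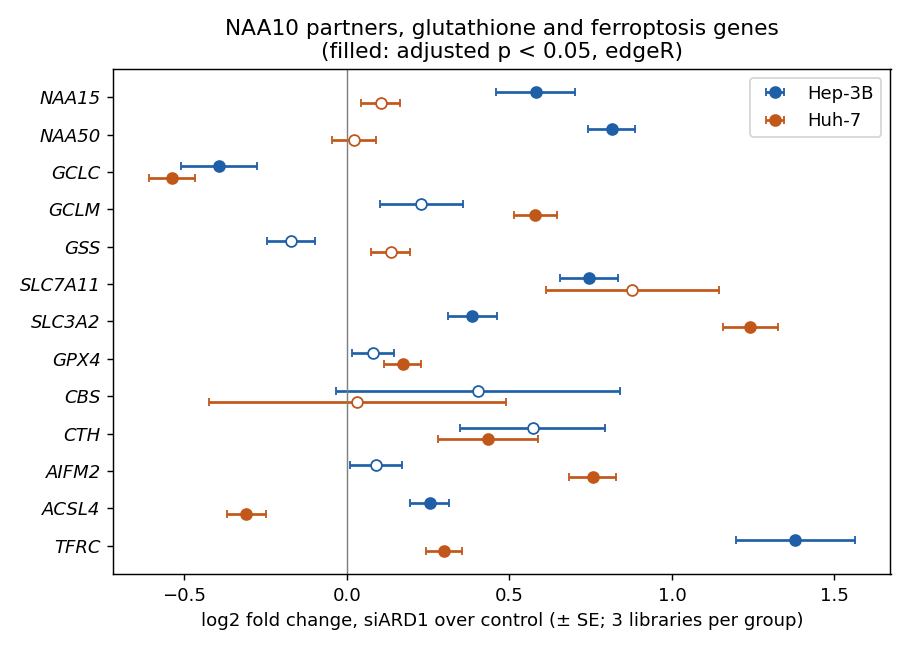
Log2 fold change (siARD1 over control, ± SE, 3 libraries per group) of 13 genes named in advance, in libraries labelled Hep-3B (blue) and Huh-7 (orange). Filled points passed the edgeR test. GCLC lies below 0 in both lines, and SLC3A2 and TFRC lie above 0 in both.

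Of 15762 genes tested in the libraries labelled Hep-3B, 5070 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 2654 higher and 2416 lower after siARD1 (52.3% higher, or 44.9% of those called with upper-quartile scaling). Of these, 269 rose and 155 fell at least 2-fold. In 7099 tested genes (45.0%, against 10% by chance) the 3 siARD1 values lay on one side of the 3 control values. Of 36 lists, 11 passed camera's test with a preset correlation of 0.01, 2 up and 9 down. With estimated correlations camera called 0, with 3 lists at an unadjusted p under 0.05, and fry called 16 for a shift in one direction. Adjusted over the list alone, counts of changed members of the lists named here were the same except for ATF4 targets (16 up), the unfolded protein response (20 up, 1 down), fatty acid synthesis (12 down), ribosomal proteins (25 down), mitochondrial mRNAs (6 down), NF-kB genes (8 down) and ferroptosis promoters (6 down). NRF2 targets, which encode antioxidant enzymes, were not called as a list, with 4 of 31 higher and 13 lower (median -0.11, camera adjusted p = 0.0853). UGDH (-0.56) and TKT (-0.51) were among those that fell, and the list passed as lower with the 22 members in no other list alone (adjusted p = 0.00205), while the whole list had an adjusted p of 0.756 with an estimated correlation. Also not called were the N-terminal acetyltransferase list (4 up and 2 down of 13, adjusted p = 0.790, median -0.01, mean -0.04, camera direction up), ferroptosis suppressors (6 up and 6 down of 25, 0.822) and ferroptosis promoters (5 up and 5 down of 22, 0.822, median -0.02, mean 0.02). Among markers of other cell types, 1 of 8 fibroblast genes rose (camera adjusted p = 0.593), 3 of 5 endothelial genes rose and 1 fell (0.222), 1 of 5 keratinocyte genes rose and 1 fell (0.822), and 0 of 4 leukocyte genes changed, too few for a list test.

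The same question was asked in Huh-7, where NAA10 fell from 174 ± 23.4 to 11 ± 1.87 CPM (SD, n = 3 each), a log2 fold change of -3.98 (SE 0.13, edgeR adjusted p = 1.66e-08), which left 6.34% of the control level (95% interval 5.30 to 7.58). The exact two-sided permutation test gave p = 0.1, the smallest this design allows. The largest rise under the same rule was in the aldo-keto reductase gene AKR1B10, from 0.161 to 15.4 CPM (log2 fold change 6.67, 9 counts over the 3 controls and 887 after siARD1). Other large rises were in the natriuretic peptide gene NPPB (3.56), ANKRD1 (3.40), the annexin gene ANXA1 (2.95), the chemokine gene CXCL8 (2.40), AKR1C2 from 95.8 to 476 CPM (2.31) and RASD1 (2.21). Their SEs, AKR1B10 included, were 0.06 to 0.31 and edgeR adjusted p from 9.10e-18 to 1.12e-08. With 9 control counts, the SE derived for AKR1B10 understates its uncertainty. Large falls besides NAA10 were in the trefoil factor gene TFF2 (-2.41), ICAM5 (-2.20), the cytokine gene LIF (-2.04), the collagen gene COL11A1 (-2.02), AGXT, which encodes a glyoxylate-detoxifying liver enzyme (-1.81), and AMH (-1.77), with SEs of 0.10 to 0.30 and edgeR adjusted p from 2.77e-12 to 0.00205. AKR1B10 and AKR1C2 have close relatives in the genome, so the share of reads given to each is uncertain.

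Targets of ATF4 rose in Huh-7, 26 of 33 with 0 falling (median 0.53). The stress cofactor gene NUPR1 rose by 1.76, SLC3A2 by 1.24, PPP1R15A by 0.93 and the tryptophanyl-tRNA synthetase gene WARS1 by 0.82 (camera adjusted p = 3.62e-10, and adjusted p = 0.521 with an estimated correlation). NRF2 targets rose in 21 of 31 with 1 falling (median 0.39), among them AKR1B10, AKR1C2, AKR1C1 (1.43) and the thioredoxin reductase gene TXNRD1 (0.90), with camera adjusted p = 6.54e-08 and adjusted p = 0.0892 with an estimated correlation. Heat shock genes rose in 12 of 18 with 1 falling (median 0.29), among them SQSTM1 (1.41), HSPH1 (0.65) and HSPA8 (0.53), with camera adjusted p = 0.000144 and adjusted p = 0.383 with an estimated correlation. Metallothionein and selenoprotein genes rose in 12 of 21 with 1 falling (median 0.21), among them the metal-binding MT1X (2.08) and MT1F (1.11), with camera adjusted p = 0.00139 and adjusted p = 0.383 with an estimated correlation. Autophagy and lysosome genes rose in 14 of 26 and fell in 3 (median 0.18), among them the sialidase gene NEU1 (1.09), with camera adjusted p = 0.00397 and adjusted p = 0.383 with an estimated correlation.

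Inflammation, mesenchymal and cell cycle entry genes rose in Huh-7. NF-kB genes rose in 10 of 19 with 1 falling (median 0.28), CXCL8 and ICAM1 (0.71) among them (camera adjusted p = 0.00479, and adjusted p = 0.581 with an estimated correlation). Mesenchymal genes rose in 10 of 22 and fell in 3 (median 0.25), among them THBS1 (2.04) and CCN2 (1.48), with camera adjusted p = 0.00701 and adjusted p = 0.383 with an estimated correlation. Interferon-stimulated genes rose in 12 of 26 and fell in 4 (median 0.33), OAS3 among the former (0.52), with camera adjusted p = 0.0221 and adjusted p = 0.383 with an estimated correlation. DNA replication and G1/S genes rose in 14 of 31 and fell in 3 (median 0.18), CDK4 among the former (0.47), with camera adjusted p = 0.00602 and adjusted p = 0.644 with an estimated correlation. Genes of G2/M and mitosis fell in 13 of 30 and rose in 2 (median -0.14), among them the kinesin gene CENPE (-0.64), with camera adjusted p = 0.0294 and adjusted p = 0.598 with an estimated correlation.

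Genes of secreted liver proteins and of lipid synthesis fell in Huh-7. Secreted liver proteins fell in 20 of 30 with 0 rising (median -0.33), among them the plasminogen gene PLG from 152 to 61.0 CPM (-1.32) and APOC3 (-1.04), with camera adjusted p = 1.81e-06 and adjusted p = 0.581 with an estimated correlation. Cholesterol synthesis genes fell in 12 of 25 and rose in 2 (median -0.17), among them INSIG1 (-0.73), with camera adjusted p = 0.00602 and adjusted p = 0.592 with an estimated correlation. Fatty acid synthesis genes fell in 12 of 19 and rose in 2 (median -0.33), among them ACSS2 (-0.76) and SREBF1 (-0.56), with camera adjusted p = 0.0109 and adjusted p = 0.521 with an estimated correlation. Hypoxia-induced genes fell in 13 of 27 and rose in 1 (median -0.34), among them BNIP3L (-0.88) and LOX (-0.87), with camera adjusted p = 0.00253 and adjusted p = 0.581 with an estimated correlation. Histone genes fell in 5 of 17 (median -0.41), H2BC5 among them (-0.40), with camera adjusted p = 0.0188 and adjusted p = 0.383 with an estimated correlation. The limit given for histones in the other line holds here too (0.0120% of control counts for the genes of the list). Glycolysis genes fell in 9 of 20 and rose in 1 (median -0.21), the liver pyruvate kinase gene PKLR among them (-1.04), with camera adjusted p = 0.0294 and adjusted p = 0.702 with an estimated correlation.

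For glutathione and ferroptosis in Huh-7, SLC3A2 rose by 1.24 (SE 0.08, edgeR adjusted p = 1.70e-07), AIFM2, which encodes the ubiquinone reductase FSP1, by 0.76 (0.07, 3.93e-08), and GCLM, the regulatory subunit beside GCLC, by 0.58 (0.07, 4.35e-07). GCLC fell by 0.54 (0.07, 2.92e-06) and ACSL4 by 0.31 (0.06, 0.000268), while TFRC rose by 0.30 (0.05, 0.000154). CTH, which makes cysteine from cystathionine, rose by 0.43 (0.15, 0.0467) and the lipid peroxide reductase gene GPX4 by 0.17 (0.06, 0.0218). CTH was lost without control 1 (adjusted p = 0.168), control 2 (0.141), siARD1 library 1 (0.24, adjusted p = 0.0943) or siARD1 library 2 (0.109), and in 3 other settings. GPX4 was lost without control 1 (adjusted p = 0.0854), control 3 (0.0568), siARD1 library 1 (0.0659) or siARD1 library 3 (0.0718), with upper-quartile scaling (0.11, adjusted p = 0.129) and with both lines in one fit (0.0698). TFRC was lost with both lines in one fit (0.28, edgeR adjusted p = 0.169). Log2 fold changes that did not pass were SLC7A11 0.88 (SE 0.27, edgeR adjusted p = 0.0624), GSS 0.14 (0.06, 0.0789), CBS 0.03 (0.46, 0.964), NAA15 0.10 (0.06, 0.175) and NAA50 0.02 (0.07, 0.811). SLC7A11 passed with DESeq2 (adjusted p = 0.00371), with both lines in one edgeR fit (0.0134) and without siARD1 library 3 (1.08, adjusted p = 0.00332). CBS was -0.53 without siARD1 library 2 (edgeR adjusted p = 0.0175).

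In the glutathione synthesis and cystine supply list of Huh-7, 6 of 14 members rose and 2 fell, or 8 and 2 adjusted over the list alone (median 0.35, camera adjusted p = 0.0351, and adjusted p = 0.383 with an estimated correlation). The call was lost without control 1 (median 0.10, adjusted p = 0.0932), control 3 (0.0537), siARD1 library 1 (0.0526) or siARD1 library 2 (0.0716), and with the 8 members in no other list (median 0.09, adjusted p = 0.374). Of ferroptosis suppressors 11 of 24 rose and 3 fell, with AIFM2, SLC3A2 and TXNRD1 among the former (median 0.16, camera adjusted p = 0.0476, and adjusted p = 0.402 with an estimated correlation). That call was lost without control 1 (adjusted p = 0.110) or siARD1 library 1 (0.0546), with a stricter count filter (0.0682) and with the members in no other list (0.0998).

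**Figure D3:**
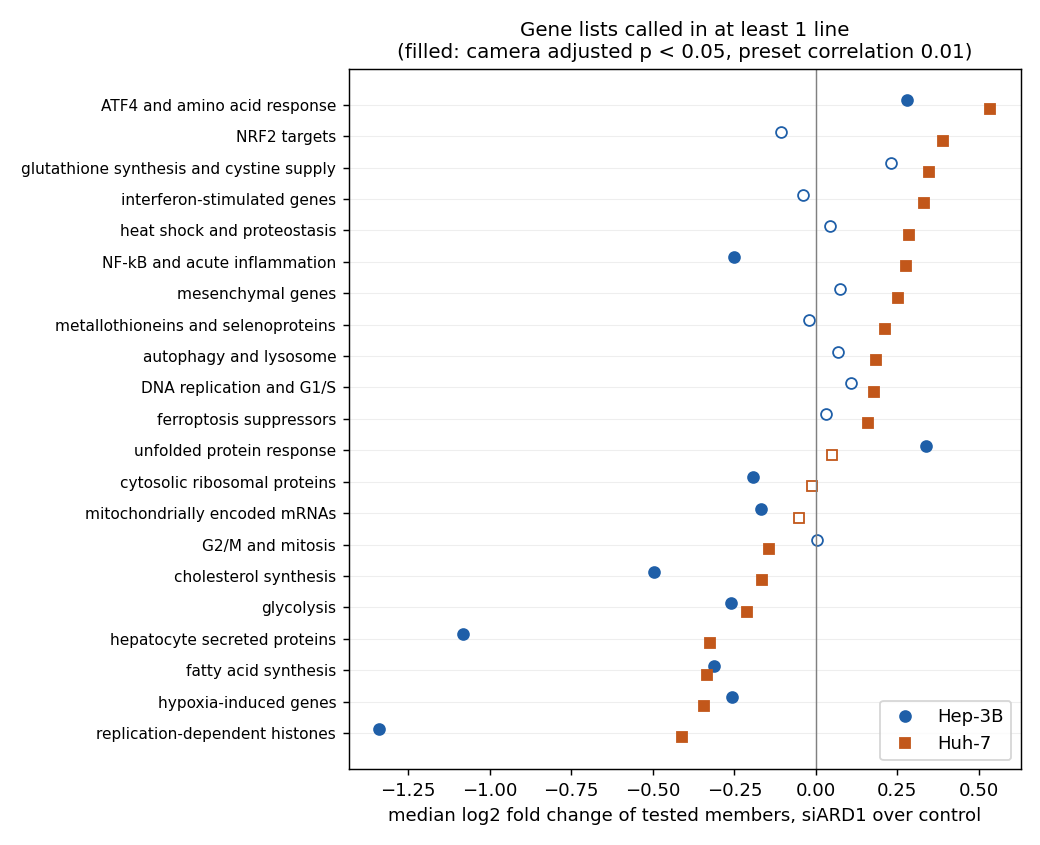
Median log2 fold change of the tested members of the 21 lists called in at least 1 line, libraries labelled Hep-3B as circles and Huh-7 as squares. Filled symbols passed camera with a preset correlation of 0.01. NRF2 targets have a median of 0.39 in Huh-7 and -0.11 in the libraries labelled Hep-3B.

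Of 15919 genes tested in Huh-7, 6388 passed edgeR's test after Benjamini-Hochberg adjustment, 3379 higher and 3009 lower after siARD1 (52.9% higher, or 39.7% of those called with upper-quartile scaling). Of these, 185 rose and 498 fell at least 2-fold. In 7959 tested genes (49.997%, against 10% by chance) the siARD1 and control values did not overlap. Of 35 lists, 18 passed camera's test, 11 up and 7 down, and with estimated correlations camera called 0, with 4 at an unadjusted p under 0.05, while fry called 23. Adjusted over the list alone, counts of changed members of the lists named for Huh-7 were the same except for the glutathione list, given above, ATF4 targets (29 up), NRF2 targets (24 up), metallothioneins and selenoproteins (13 up), interferon-stimulated genes (13 up), ferroptosis suppressors (12 up, 4 down), G1/S genes (17 up), G2/M genes (4 up, 14 down), secreted liver proteins (21 down), hypoxia-induced genes (14 down), glycolysis (10 down), histones (4 down), the unfolded protein response (2 up), ribosomal proteins (1 up), mitochondrial mRNAs (0 down) and drug and bile acid metabolism (3 down). The G2/M call was lost without control 2 (adjusted p = 0.0706), control 3 (0.0587), siARD1 library 1 (0.0546) or siARD1 library 2 (0.0826), and with both lines in one fit (0.0842). The glycolysis call was lost without control 2 (adjusted p = 0.0852), siARD1 library 1 (median -0.11, adjusted p = 0.128) or siARD1 library 2 (0.122), with no filter (0.196), with both lines in one fit (0.187) and with the members in no other list (0.0567). Lists not called included the unfolded protein response (3 up and 4 down of 23, adjusted p = 0.854), ribosomal proteins (2 up and 2 down of 49, 0.893), mitochondrial mRNAs (1 down of 13, 0.307), the N-terminal acetyltransferase list (4 up and 4 down of 14, 0.981, median 0.07, mean -0.32, camera direction up) and ferroptosis promoters (10 up and 5 down of 22, 0.395). Other liver lists were not called either, drug and bile acid metabolism (4 up and 4 down of 25, camera adjusted p = 0.596), liver transcription factors (2 up and 5 down of 17, 0.304) and fatty acid oxidation (3 up and 6 down of 25, 0.376). Among markers of other cell types, 4 of 7 fibroblast genes fell (camera adjusted p = 0.107), 1 of 5 keratinocyte genes rose and 1 fell (0.981), 2 of 4 endothelial genes fell and 0 of 4 leukocyte genes changed.

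Comparing the lines asked which changes were shared. Genes that rose in both included CREB5 (log2 fold changes 1.05 in the libraries labelled Hep-3B and 1.23 in Huh-7), the uridine phosphorylase gene UPP1 (1.03 and 0.98), SEMA7A (1.59 and 0.89), the fructose bisphosphatase gene TIGAR (1.45 and 0.84), WARS1 (0.93 and 0.82) and the sulfotransferase gene CHST3 (0.76 and 1.33). Genes that fell in both included, after NAA10, the plasma glycoprotein gene LRG1 (-1.11 and -0.91), the junction gene TJP3 (-0.85 and -0.83), SYT17 (-0.80 and -0.95) and the histone gene H2BC21 (-1.22 and -0.79). The Hep-3B call of WARS1 (edgeR adjusted p = 0.0409) was lost without siARD1 library 1 (0.121), 2 (0.119) or 3 (0.135) and with no filter (0.0899). Of 13800 genes tested in both, 628 rose in both lines where 580 would by chance (Fisher's exact test across genes, two-sided, odds ratio 1.14, p = 0.0119), and 509 fell in both where 409 would (odds ratio 1.396, p = 5.36e-09). Genes are not independent replicates. Opposite changes were about as many, 1069 against 976 by chance, next to 1137 in the same direction. Opposite changes outnumbered shared ones without Hep-3B control 1 (1124 against 1015), Huh-7 control 2 (994 against 947), Huh-7 siARD1 library 1 (1000 against 975) or Huh-7 siARD1 library 2 (1042 against 957). Across genes the log2 fold changes of both lines had a Pearson r of 0.0498 and a Spearman rho of 0.0365. That r was -0.000242 without Hep-3B control 1 and 0.0899 without Hep-3B control 3.

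**Figure D4:**
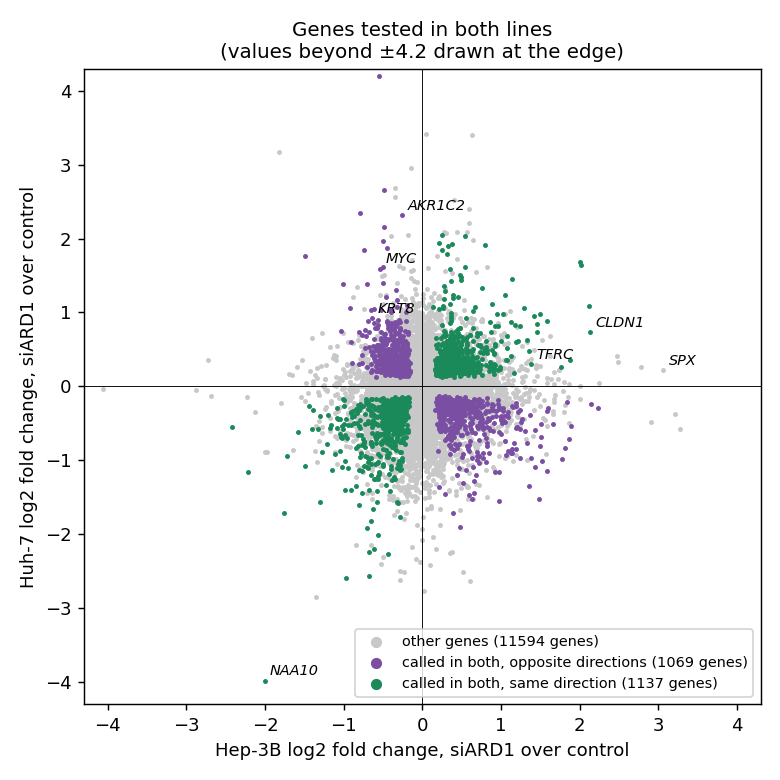
Log2 fold change in Huh-7 against that in the libraries labelled Hep-3B for the 13800 genes tested in both. Green points were called in both in the same direction (1137), purple points in opposite directions (1069), grey points are the other genes, and 1 gene is drawn at the edge. The cloud has almost no tilt, with r = 0.0498.

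The last comparison tested whether the siARD1 effect differed between the lines (Huh-7 effect minus Hep-3B effect on the log2 scale). The fall in NAA10 was deeper in Huh-7 by -2.0 (edgeR adjusted p = 1.56e-05). Among glutathione and ferroptosis genes, the effect was higher in Huh-7 for SLC3A2 (0.84, edgeR adjusted p = 5.94e-05), AIFM2 (0.65, 5.35e-05) and GSS (0.29, 0.0222), and lower for TFRC (-1.10, 0.00239), ACSL4 (-0.58, 1.12e-05), NAA50 (-0.81, 3.59e-06) and NAA15 (-0.49, 0.0228). The GSS difference was lost without Hep-3B siARD1 library 2 (adjusted p = 0.0646), Huh-7 control 1 (0.0866) or Huh-7 siARD1 library 3 (0.0707), and the NAA15 difference without Hep-3B control 3 (0.0681), Huh-7 siARD1 library 1 (0.0540) or Huh-7 siARD1 library 3 (0.0614). Differences that did not pass were GCLC -0.16 (edgeR adjusted p = 0.409), GCLM 0.33 (0.126), SLC7A11 0.12 (0.808), GPX4 0.07 (0.587), CTH -0.16 (0.771) and CBS -0.39 (0.699). The GCLC difference passed without Hep-3B siARD1 library 1 (-0.31, edgeR adjusted p = 0.0442). The GCLM difference passed with DESeq2 (0.36, adjusted p = 0.0423) and without Hep-3B control 1 (0.49, adjusted p = 0.000207).

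The largest differences by rule were AKR1B10 (7.21), APOA2 (5.88), AKR1B15 (5.16), RFPL4B (4.30), A2M (3.99) and L1CAM (3.68) upwards, and ZNF813 (-3.54), ZNF542P (-3.54), PCLO (-3.41), DLX6-AS1 (-3.11), TMEM45B (-3.09) and SPX (-2.86) downwards. Several rest on few counts in one line. In the libraries labelled Hep-3B, controls and siARD1 summed to 21 and 0 counts for APOA2, 66 and 4 for A2M, 5 and 0 for RFPL4B, 2 and 32 for ZNF813, 0 and 6 for ZNF542P, 1 and 12 for DLX6-AS1, and 4 and 19 for TMEM45B. In Huh-7 they summed to 0 and 7 for each of AKR1B15 and L1CAM. Where a group holds 0 counts, as for APOA2, RFPL4B, ZNF542P, AKR1B15 and L1CAM, the fitted difference depends on the prior count and is no bound. APOA2 and A2M are abundant in Huh-7, and their Hep-3B counts stand at the trace level described for ALB. AKR1B15 is a near relative of AKR1B10. Of the 12 fits that each leave out 1 library, 5 ended the call of L1CAM (highest adjusted p = 0.118, without Huh-7 siARD1 library 2), 4 that of RFPL4B (0.113, without Hep-3B control 1), 11 that of ZNF542P (0.203, without Hep-3B siARD1 library 3) and 1 that of AKR1B15 (0.0971, without Huh-7 siARD1 library 1). With limma-voom L1CAM was 1.46 (adjusted p = 0.230) and ZNF542P -1.24 (0.265). The ZNF542P call was also lost with DESeq2 (-2.74, adjusted p = 0.0981), with RLE factors (0.0502) and with no filter (0.0634).

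Of the groups, NRF2 targets had the smallest p in camera, higher in Huh-7 in 19 of 31 and lower in 1 (median difference 0.55, camera adjusted p = 1.29e-09, and adjusted p = 0.180 with an estimated correlation). The unfolded protein response was the 1 list lower in Huh-7, in 15 of 23 genes (-0.34, camera adjusted p = 1.74e-05, and adjusted p = 0.180 with an estimated correlation). Lists higher in Huh-7 were ATF4 targets (18 of 34 higher, median difference 0.40, camera adjusted p = 0.000774), NF-kB genes (11 of 20, 0.44, 0.00188), ribosomal proteins (13 of 49, 0.12, 0.00622), mesenchymal genes (11 of 24, 0.32, 0.0130), heat shock genes (8 of 18, 0.21, 0.0170), cholesterol synthesis (12 of 25, 0.30, 0.0176), interferon-stimulated genes (9 of 30, 0.23, 0.0221), histones (4 of 18, 0.73, 0.0334), metallothioneins and selenoproteins (6 of 17, 0.26, 0.0334) and ferroptosis suppressors (9 of 25, 0.12, 0.0445). With an estimated correlation their adjusted p lay between 0.180 and 0.766. Secreted liver proteins were higher in Huh-7 in 13 of 29 and lower in 1 (0.62, camera adjusted p = 0.0130, and adjusted p = 0.602 with an estimated correlation). A further setting left out genes whose carry-over, as estimated, reached 10% of their mean level in any library. Whether their counts are carried over was not shown. The call of secreted liver proteins was lost in this setting (0.56, adjusted p = 0.0572), an alternative chosen after the data were seen. Calls were also lost for cholesterol synthesis without Hep-3B control 1 (adjusted p = 0.0892), for histones without Hep-3B control 2 (0.145), for heat shock genes without Hep-3B control 1 (0.0840), for metallothioneins without Huh-7 control 1 (0.0776) and for ribosomal proteins without Hep-3B siARD1 library 2 (0.06, adjusted p = 0.0709) or Huh-7 control 1 (0.06, adjusted p = 0.0740). The call of ferroptosis suppressors was lost without any of 5 libraries (adjusted p = 0.0509 to 0.0922). With only members in no other list, calls were lost for ferroptosis suppressors (0.196), heat shock genes (0.11, adjusted p = 0.0548) and metallothioneins (0.124).

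Of 17122 genes tested, 5380 differed between the lines by edgeR's quasi-likelihood test after adjustment, 2607 with a higher effect in Huh-7 and 2773 with a lower one. Of 2495 genes called in the libraries labelled Hep-3B and not in Huh-7, 1618 passed the test of the difference, as did 1928 of the 3562 called in Huh-7 and not in the other line. Of 36 lists, 13 passed camera's test, and with estimated correlations camera called 0, with 3 at an unadjusted p under 0.05, while fry called 15.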

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

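Between the lines, named here by their labels, the siARD1 effect differed for many genes. Each difference listed in this part stands here because a test of the difference itself passed. The tests of RNA carried over between the lines and of basal NRF2 target levels were chosen only after the result was seen. Of 17122 genes tested, 5380 differed. In 40 relabellings of the libraries within each line, the labelled one included, 1 gave as many, and the highest other gave 1411. Relabelling a line takes away its siARD1 effect along with any difference, so these splits decide nothing about a difference between the lines. For the 1137 changes shared by both lines they decide nothing either. Relabelling either line left 0 genes called in it and so 0 shared, and the highest other of 100 relabellings (1069) is the labelled split with the direction of 1 line turned. For each line alone, 10 splits of 3 against 3 are too few for a share under 0.05. The labelled split gave 5070 genes and the highest other 0 in the libraries labelled Hep-3B, and 6388 and 0 in Huh-7. For gene lists the labelled split gave 11 and the highest other 9, and in Huh-7 18 and 14. Camera with the preset correlation thus also called lists in splits where 0 genes passed.

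By list, the effect was higher in Huh-7 for NRF2 targets (median difference 0.55), ATF4 targets (0.40), NF-kB genes (0.44), secreted liver proteins (0.62), histones (0.73), mesenchymal genes (0.32), cholesterol synthesis (0.30), metallothioneins and selenoproteins (0.26), interferon-stimulated genes (0.23), heat shock genes (0.21), ribosomal proteins (0.12) and ferroptosis suppressors (0.12). It was lower for the unfolded protein response (-0.34). None of these passed with an estimated correlation in camera (3 at an unadjusted p under 0.05), and fry called 15 of 36 lists.

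Secreted liver protein mRNAs fell in 14 of 18 tested genes in the libraries labelled Hep-3B, by 618 CPM when summed. Against Huh-7 RNA carried over into the control libraries as the whole cause, the estimated carry-over predicted 2.06% of that fall. That estimate and the predictions by member rest on 28 genes that include list members, ALB, AFP and AMBP among them. They are therefore not independent of the list, and for these members least of all. Abundant genes such as FGB (325 to 137 CPM) carry this sum, so it says little about weak members. By member, carry-over predicted under 10% of the control level for 12, of which 10 fell. It predicted 57.4% for AMBP and 11.2% for AGT, which also fell. Against a trend on GC content or gene length as the whole cause, the median log2 fold change was -1.05 once that trend was removed. For ALB and AFP alone, carried-over Huh-7 RNA is a candidate explanation of their control level, since 17 other Huh-7-specific genes (median ratio 0.0466% in controls, 0.0211% after siARD1) predicted 114% of it, although 311% of their level after siARD1. A response of the cells to siARD1 stays open for the other members, beside partial carry-over for AMBP and AGT. So does a difference in handling between the groups, which cannot be told apart from siARD1 in this line.

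NRF2 targets rose in 21 of 31 genes in Huh-7, while 4 rose and 13 fell in the libraries labelled Hep-3B. Against carried-over Hep-3B RNA, the highest estimated share in a Huh-7 siARD1 library was 0.0565%, where the rise of AKR1B10 would need 5.61%. Against a GC or length trend, the median difference over 30 targets was 0.59 once the trend was removed and 0.52 before. A candidate explanation is that the targets already stood high in the libraries labelled Hep-3B, where 29 of 31 had higher control levels (median log2 ratio 2.19, random lists -0.16). The deeper fall of NAA10 in Huh-7 stays open beside it, untested.

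The log2 fold changes of both lines were almost unrelated across genes (Pearson r = 0.0498). Against replicate noise, single pairs of libraries within a line gave correlated fold changes, with a median r of 0.503 in the libraries labelled Hep-3B and 0.625 in Huh-7 over 18 combinations each, where the between-line median was 0.0352 over 81. Against a GC or length trend, r was 0.0583 with the trend removed from each line. Against weakly expressed genes, r was 0.0463 among the 6458 genes with at least 20 CPM in both lines. The lines themselves and the depth of the knockdown relative to control stay open, since the design changes both together. The difference in handling that cannot be told apart from siARD1 in the libraries labelled Hep-3B stays open too. It would also give correlated fold changes within that line.

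Of the genes named in the text, 84 had a difference that passed, 54 higher and 30 lower in Huh-7, given here as Huh-7 effect minus Hep-3B effect on the log2 scale. Higher effects in Huh-7 were fitted for AKR1B10 (7.21), APOA2 (5.88), AKR1B15 (5.16), RFPL4B (4.30), A2M (3.99), L1CAM (3.68), ANXA1 (3.07), CLIC3 (3.06), ANKRD1 (2.71), AKR1C2 (2.56) and ALB (2.54). Next came MYC (2.11), RARRES1 (2.05), CYTIP (1.93), AFP (1.85), THBS1 (1.78), CXCL8 (1.76), MT1X (1.76), RASD1 (1.60), KRT8 (1.55), NUPR1 (1.55), AKR1C1 (1.52) and SQSTM1 (1.45). Of these, CLIC3, CYTIP and RARRES1 rest on few counts in Huh-7 (2 in controls and 7 after siARD1, 23 and 29, and 48 and 71). ANKRD1 does so in the libraries labelled Hep-3B (17 and 30). ALB (301 and 51) and AFP (100 and 20) stood there at the trace level for which carry-over is a candidate explanation. The limits given above hold here too for APOA2, A2M, AKR1B15, RFPL4B and L1CAM. They also hold for ZNF542P, ZNF813, DLX6-AS1 and TMEM45B among the lower effects. Smaller positive differences were those of UGDH (1.44), KRT18 (1.43), ITIH2 (1.39), H4C8 (1.34), NFKBIA (1.23), FGB (1.19), FGA (1.16), NEU1 (1.16), H1-2 (1.05), CCN2 (0.97), H2BC5 (0.89) and ICAM1 (0.88). These were followed by SLC3A2 (0.84), TXNRD1 (0.81), AIFM2 (0.65), C3 (0.64), NFE2L2 (0.62), SREBF1 (0.60), TNFAIP3 (0.60), PPP1R15A (0.59), TKT (0.59), SCD (0.58), PKM (0.57) and CHST3 (0.56). The list goes on with HSPA8 (0.56), FDFT1 (0.54), OAS3 (0.47), FADS2 (0.45), RPS14 (0.39), SREBF2 (0.30) and GSS (0.29). Lower effects in Huh-7 were fitted for ZNF542P (-3.54), ZNF813 (-3.54), PCLO (-3.41), DLX6-AS1 (-3.11), TMEM45B (-3.09), SPX (-2.86), IER3IP1 (-2.65), ICAM5 (-2.38), LIF (-2.19), SLC16A9 (-2.09) and NAA10 (-2.0). Less negative were CLGN (-1.88), ABCA10 (-1.87), FBXW10B (-1.77), CENPE (-1.67), AMH (-1.5), CLDN1 (-1.42), SEL1L (-1.29), DNAJB9 (-1.13), TFRC (-1.10), BNIP3L (-1.09), LOX (-0.82) and NAA50 (-0.81). The rest were SEMA7A (-0.72), TIGAR (-0.63), ACSL4 (-0.58), NAA15 (-0.49), NDRG1 (-0.48), HYOU1 (-0.44) and ACSS2 (-0.35).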

How the results depend on the processing

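The alternative that leaves out carry-over genes was chosen after the data were seen, and the other settings before the data were examined. NAA10 kept its call in every setting run, from -2.11 to -1.88 in the libraries labelled Hep-3B and from -4.13 to -3.86 in Huh-7 with each library left out in turn. Counts of changed genes then ran from 3695 to 4922 and from 5249 to 6137, of differing genes from 4739 to 5579, and of shared changes from 840 to 1238. Lists called ran from 10 to 12, from 15 to 18, and from 10 to 13 for the difference. Other tools gave 4545 and 5385 genes (DESeq2), or 5037 and 6383 (limma-voom), and leaving out carry-over genes 5057 and 6384. At a fold of at least 1.5 the counts were 1385 (849 higher, 536 lower) and 1910 (674 higher, 1236 lower), since fewer genes reach it. At a false discovery rate of 0.01 in both lines 491 changes were shared (269 higher, 222 lower) and 472 were opposite, for the same reason. With an estimated correlation camera called 0 lists in the libraries labelled Hep-3B, 0 in Huh-7 and 0 for the difference. The glutathione list in Huh-7 lost its call there (median 0.35, adjusted p = 0.383), and with members of another list left out (median 0.089), where fewer genes are tested. Its median ran from 0.10 to 0.43 with each library left out.

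Values that changed sign were near 0 or uncertain, and the cause was not tested. In Huh-7, NAA50 was -0.040 and CBS -0.029 with upper-quartile factors, and CBS -0.11 with limma-voom. With each library left out, NAA50 ran from -0.047 to 0.094, CBS from -0.53 (without siARD1 library 2, edgeR adjusted p = 0.0175) to 0.31, APOA2 from -0.15 to 0.021 and DLX6-AS1 from -0.089 to 0.041. The differences of SLC7A11 and CTH ran from -0.053 to 0.31 and from -0.36 to 0.096. A term for replicate number, a replicate block, gave 5597 and 6328 genes and CBS -0.077 in Huh-7. With it edgeR no longer called WARS1 in the libraries labelled Hep-3B (0.97, adjusted p = 0.101) nor the ZNF542P difference (-3.34, 0.0651), camera no longer called the ferroptosis suppressor difference (0.12, 0.0643), and edgeR called SLC7A11 (0.85, 0.0183) and PCLO (-0.49, 0.00175) in Huh-7. Replicate numbers were not treated as paired, since same-number correlations of residuals were 0.0344, 0.0652 and 0.0643 in the libraries labelled Hep-3B and 0.0520, -0.0646 and 0.00746 in Huh-7, under the 0.1 set for pairing. Different-number correlations ran from -0.0548 to -0.0103 in the libraries labelled Hep-3B, all below the same-number ones, and from -0.103 to 0.108 in Huh-7. A weak pairing in the libraries labelled Hep-3B is thus not excluded. Counted as combinations of a result and a setting, single-gene calls were lost in 103 and gained with the same sign in 16. The CBS call in Huh-7 without siARD1 library 2, with its sign turned, comes on top of these. List calls were lost in 80 with settings fixed in advance, 42 of these with the estimated correlation, and in 1 with carry-over genes left out. At these depths a gene needed about 0.457 CPM (Hep-3B) or 0.509 CPM (Huh-7) to be tested, so changes in weaker genes were not detectable.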

Other observations

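Keratin and MYC mRNAs moved in opposite directions in the lines, and the genes of this paragraph were grouped after their values were seen. KRT8 and KRT18, the keratins of simple epithelia, rose by 0.92 and 1.04 on the log2 scale in Huh-7 and fell by 0.64 and 0.41 in the libraries labelled Hep-3B (edgeR adjusted p = 1.47e-10, 2.34e-11, 5.46e-06 and 0.000301). MYC rose by 1.59 in Huh-7 and fell by 0.53 in the other line (edgeR adjusted p = 4.71e-06 and 6.96e-05). CENPE, a kinesin of mitotic chromosomes, fell by 0.64 in Huh-7 and rose by 1.01 in the libraries labelled Hep-3B (edgeR adjusted p = 3.77e-05 and 0.000373). NFE2L2, the gene of NRF2 itself, rose by 0.66 in Huh-7 (edgeR adjusted p = 9.01e-09) and had a log2 fold change of 0.03 in the libraries labelled Hep-3B (0.734). ANKRD1, CCN2 and THBS1, known targets of the YAP coactivator, rose by 3.40, 1.48 and 2.04 in Huh-7. In the libraries labelled Hep-3B CCN2 rose by 0.49 and THBS1 by 0.25, and ANKRD1 had 0.63 without passing (edgeR adjusted p = 0.489).

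Mitochondrial mRNAs made up 6.10 ± 0.257% of counts in the controls labelled Hep-3B and 5.52 ± 0.127% after siARD1, and 7.62 ± 0.0613% and 7.02 ± 0.152% in Huh-7 (SD, n = 3, exact permutation p = 0.1 in each line, the smallest possible). The genes of the fixed histone list made up 0.00958% and 0.00425% of counts in the libraries labelled Hep-3B, and 0.0120% and 0.00937% in Huh-7. MALAT1 and NEAT1 together made up 0.00954% of counts in the Hep-3B controls and 0.00876% after siARD1 (exact permutation p = 0.6). In Huh-7 they made up 0.0287% and 0.0204% (exact permutation p = 0.1). All these libraries are labelled as total RNA depleted of rRNA. In the libraries labelled Hep-3B the log2 fold change followed GC content across genes (Spearman rho -0.292, with 9.55% of deviance explained by GC and length), and in Huh-7 hardly (-0.00368, 1.91%). After removal of that trend all 11 and 18 called lists kept the sign of their median. Some medians shrank in the libraries labelled Hep-3B, as for ribosomal proteins (-0.19 to -0.12) and mitochondrial mRNAs (-0.17 to -0.11).

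A hypothesis, with its test chosen before the result was seen, was that genes lower in both lines share seed matches to the siRNA, whose sequence is not given in the sources used here. Every 7-mer of the NAA10 mRNA was therefore scored against 3' UTRs in both lines. The lowest z of any of them, taking the weaker line, was -1.77, far from the -4 set in advance, which argues against a strong seed effect of a siRNA that matches NAA10 over its whole length.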
